A study of Mus musculus with 6 samples.

How the data were processed

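Hearts of 3 control mice with loxP-flanked Elac2 and no cre and of 3 mice that also carried cre were compared; the labels name no batch, day or litter. Per the labels' protocols, total RNA was taken from heart with a miRNeasy kit, small RNA libraries were size-selected for 15 to 35 nt and sequenced in pairs on an Illumina instrument, with 4 technical replicates per mouse. Per the file headers there is 1 column per mouse; how the technical replicates were combined is not given in the sources used here. Per the submitters' processing notes, Bowtie2 2.2.9, cutadapt 1.1.4 and DESeq2 1.16.1 were used with build mm10; the notes give no order, and the set of tRF sequences and the mapping rules are not given in the sources used here. A read that fits several near-identical tRNA copies cannot be traced to 1 gene, so values of close variants depend on how the authors assigned such reads.

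The authors deposited raw counts per sequence (unit counts), normalized counts (unit signal) and a table of their own comparison. The authors' normalized signal is the raw count divided by 1 size factor per library: the ratio of the pair was constant within a library to a relative 7.5e-11, and the factors equalled DESeq2's median-of-ratios factors on these counts. The authors' deposited table gives sequence length, mean normalized signal, log2 fold change and its standard error, a Wald score, and raw and adjusted p-values; 804 of 1336 sequences have no adjusted p there, and these stayed out of counts. All deposited columns belong to the 6 libraries. A library's total here is the sum of its tRF counts, 235046, 773252 and 378924 in controls and 55946, 45354 and 61712 in knockouts, not its sequencing depth. A count of 0 allows up to 3 counts, which is 0.000388% to 0.00661% of a library's tRF count; such limits and the counting intervals cover counting error only. Of the sequences, 205 are longer and 14 shorter than the size selection.

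Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood method with group as the only term, TMM scaling and filterByExpr (minimum count 10), with Benjamini-Hochberg adjustment at 0.05. The filter passed 254 sequences. Its limit is relative to each library's total tRF count. A knockout library, with its lower total, therefore passes with fewer counts than a control library, which favours sequences high in the knockout. TMM factors were 1.02, 0.215 and 0.400 in controls and 2.41, 2.56 and 1.85 in knockouts. CPM is relative to the TMM-scaled total. The SE is the absolute log2 fold change divided by the root of the quasi-likelihood F. Sets were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1), in sets of at least 5 tested sequences. Shares and sums were compared with exact two-sided permutation tests over 20 assignments (SciPy 1.17.1), where the smallest p is 0.10. Data were also simulated with the same dispersion of 0.363 for each sequence. With 239 testable sequences the edgeR step recovered 30 of 31 changes of 4 and 8 of 24 changes of 2 on the log2 scale, and called 1 of 184 unchanged sequences.

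The tests, their alternatives and the rule for naming fragments were set before the data were examined. The rule names, among called fragments whose groups do not overlap, the 10 with the largest and the 10 with the smallest log2 fold change. It adds the 5 fragments with the highest mean CPM whatever their p or overlap, and the called fragment with the lowest p in each class, which gave 24 fragments; 2 of them are not reported here. Alternatives were size factors of DESeq2, library totals alone, upper-quartile scaling, no filter, a filter of 10 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom, identical sequences collapsed, the replicate number as a block, each library left out, and a fold threshold. Parts of the work departed from the design. Sequence names give no amino acid, so amino acids of 5′ fragments were assigned from the anticodon in a hairpin of 5 bp with a 7-nt loop. It was read in 40 longer 5′ sequences and carried to sequences that are the start of these or extend them. Where none matched, the first 8 nt sufficed if the anticodons read for them gave 1 amino acid. In this way 338 of 554 were assigned, and a set whose anticodon could not be read is named by its first 8 nt. Sums per anticodon were replaced by families that share the first 15 nt (trailers and 5′ fragments) or the last 13 nt (CCA-ending fragments). Mitochondrial and microRNA sets fixed beforehand had no members, since the tables held neither kind of sequence, and tRNA fragments carry no cell type marker. Sequences were matched whole to GENCODE transcripts of GRCm38, the assembly of mm10, with tRNA gene positions from RefSeq; a genome sequence was not used here, so fragments outside transcripts have no position. A serine or glycine gene named for a fragment is a match, not proof that the fragment came from that copy.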

Results

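Small RNA from mouse heart was sequenced to ask how loss of ELAC2 changes the fragments that derive from tRNAs. ELAC2 is the RNase Z that cuts the 3′ trailer off precursor tRNAs in the nucleus and in mitochondria. An exon of the gene was flanked by loxP sites and removed with cre driven by a muscle creatine kinase promoter, so that deletion is directed to heart and skeletal muscle. There were 3 control mice, which carry the loxP sites without cre, and 3 Elac2 knockout mice, all on a C57BL/6 background, and each mouse gave 1 library. Each table held raw read counts for 1336 tRNA fragment (tRF) sequences in 3 classes. The class tRF_1 had 435 sequences, of which 43.2% ended in TTT, the terminator of RNA polymerase III, and none ended in CCA, as trailers cut from precursors do. The class tRF_3 had 347 sequences, and 100% of them ended in CCA, which is added to the 3′ end of a tRNA after the trailer is removed. The class tRF_5 had 554 sequences from the 5′ end of tRNAs. Elac2 mRNA and mitochondrial tRNAs were not analysed here: 0 of the 1336 sequences shared 15 nt with any of the 22 mouse mitochondrial tRNAs. The genotype labels could therefore not be checked against the deleted gene.

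Libraries from knockout hearts held fewer 5′ fragment counts, while trailer and CCA-ending counts overlapped between the groups. The summed tRF_5 count was 454036 ± 282190 (SD, n = 3) per control library and 46802 ± 8170 (SD, n = 3) per knockout library, a 9.70-fold lower mean, with each knockout library below each control library (exact two-sided permutation test, p = 0.10). Without control replicate 2 the mean was 6.35-fold lower. The summed tRF_1 count was 4389 ± 1704 (SD, n = 3) in control and 3725 ± 807 (SD, n = 3) in knockout libraries (exact two-sided permutation test, p = 0.70), and the tRF_3 count was 3983 ± 2590 (SD, n = 3) against 3810 ± 207 (SD, n = 3) (exact two-sided permutation test, p = 1.0). The tRF_3 mean of controls rested on control replicate 1: without it the mean was 2490, and the 3 knockout libraries lay above both other controls, 1.53-fold higher. As shares of a library's tRF count, trailers made up 1.37% ± 1.15 (SD, n = 3) in control and 6.96% ± 1.72 (SD, n = 3) in knockout hearts, and CCA-ending fragments 1.32% ± 1.44 (SD, n = 3) and 7.09% ± 0.737 (SD, n = 3). Without control replicate 1 the control means were 0.738% and 0.499%. The share of 5′ fragments was 97.3% ± 2.58 (SD, n = 3) in control and 85.9% ± 2.25 (SD, n = 3) in knockout hearts. For each class the knockout libraries lay apart from the controls, which gives p = 0.10 by the exact permutation test, raw and Benjamini-Hochberg adjusted over the 3 classes, the smallest that 3 against 3 animals allow. Total tRF counts ran from 235046 to 773252 in controls and from 45354 to 61712 in knockouts. The total small RNA depth of the libraries is unknown here, so none of these values says how a class changed per heart cell. When the single most abundant sequence was left out, the difference in share widened to 11.5 percentage points for trailers, 12.1 for CCA-ending fragments and −23.6 for 5′ fragments.

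**Figure D1:**
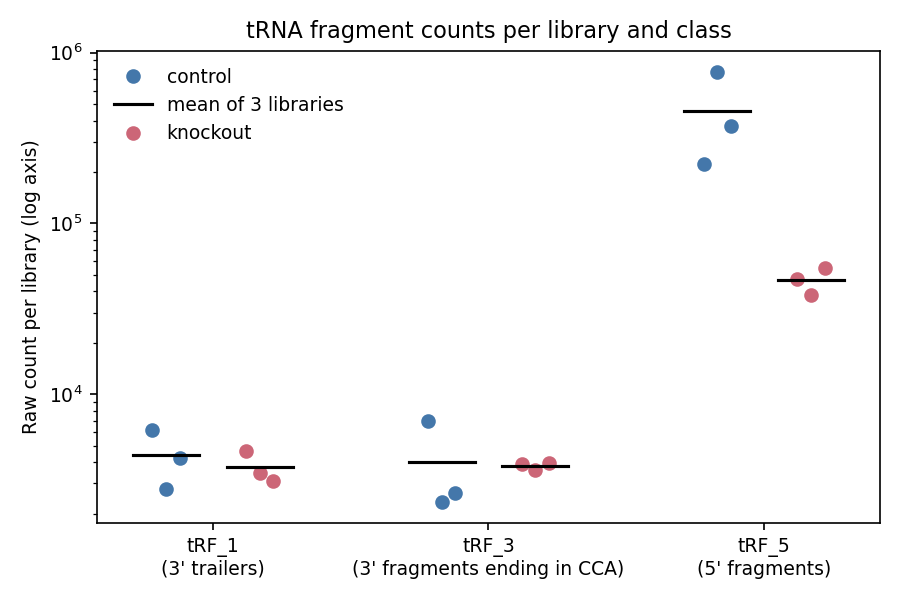
Raw counts (log axis) summed per library for the 3 fragment classes on the x axis, with 3 control libraries in blue, 3 knockout libraries in red and a black line at each mean. The tRF_5 counts of knockout libraries all lie below those of controls (means 46802 and 454036), whereas the tRF_1 and tRF_3 counts of the 2 groups overlap.

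Of 254 fragments that passed the filter, 83 changed between knockout and control hearts: 40 were higher and 43 lower in the knockout (edgeR quasi-likelihood test, TMM scaling, Benjamini-Hochberg adjusted p under 0.05). Calls among trailers and CCA-ending fragments were mostly increases, with 4 higher and 0 lower of 58 trailers and 9 higher and 1 lower of 57 CCA-ending fragments. With no filter the CCA-ending calls were 6 higher and 4 lower. Without control replicate 1, 7 trailers and 16 CCA-ending fragments were higher, and without knockout replicate 1, 2 trailers and 7 CCA-ending fragments. The 5′ fragments moved both ways, with 27 higher and 42 lower of 139. Adjusted over the list alone, edgeR called 3 trailers, 8 CCA-ending fragments and 72 5′ fragments. At an unadjusted p under 0.05, edgeR gave 8 trailers higher and 0 lower, with 12 CCA-ending fragments and 79 5′ fragments; DESeq2 called 4 trailers higher, 3 of them shared with edgeR, and limma-voom 5, and both called 0 lower. The 2 groups did not overlap in 111 fragments, or 43.7% of those tested, where chance gives 10%. The balance of directions depended on the filter and on the scaling. With no filter 25 of 1336 fragments were higher and 74 lower. With TMM the median log2 fold change of all tested fragments was 0.06, with upper-quartile scaling it was 0.43 with 52 higher and 36 lower, and with library totals alone it was 2.15 with 104 higher and 7 lower, so each change is relative to the bulk of tested fragments. Many sequences are nested in one another, and when sequences that share an end were summed into families, a step chosen after seeing the data, 17 of 89 families changed, 8 higher and 9 lower. With library totals alone 35 families were higher and 0 lower. The number lower dropped to 26 without control replicate 2 and to 27 without control replicate 3.

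The fragments with the largest increases were short CCA-ending pieces and 5′ fragments. Of the 5′ fragments, tRF_5_387 of an unassigned tRNA had the largest log2 fold change, ahead of valine and lysine fragments. The 22-nt fragment tRF_3_204 (TCGATCCCCGGCACCTCCACCA) had 42.2, 78.6 and 179 CPM (counts relative to the TMM-scaled library size) in the control libraries and rose to 4854 ± 1400 CPM (SD, n = 3) in the knockout, a log2 fold change of 5.61 ± 0.78 (SE) with edgeR adjusted p = 0.0002. The shorter form tRF_3_156 (CGATCCCCGGCACCTCCACCA) had 0 counts in all 3 control libraries and 134 counts over the knockout libraries. Taking 3 counts over the control group as the limit that a count of 0 allows, tRF_3_156 was at least 69.0-fold higher in knockout hearts (edgeR adjusted p = 0.00046). The longer form tRF_3_235 (TTCGATCCCCGGCACCTCCACCA) had 2 control counts and 43 knockout counts, a 33.2-fold ratio with a 95% counting interval of 8.65 to 283 (edgeR adjusted p = 0.0021). These 3 sequences end alike. The summed count of the 13 sequences that end in GGCACCTCCACCA rose from 638 ± 280 to 8356 ± 2004 CPM (SD, n = 3). This family had a log2 fold change of 3.70 ± 0.56 (SE) with edgeR adjusted p = 0.00069. Not each member was called: tRF_3_171, which differs from tRF_3_204 by 1 base, did not pass (log2 fold change 0.995, edgeR adjusted p = 0.37). A fragment with another 3′ end, tRF_3_62 (AACCGGGCGGGAACACCA), was 20.1-fold higher (95% counting interval 5.03 to 175, 2 control counts, edgeR adjusted p = 0.0033), and its family ending in GGCGGGAACACCA rose by 3.99 ± 0.58 (SE) on the log2 scale (edgeR adjusted p = 0.00068). The fragment tRF_3_86 (GTCCCGCCAGAGTCGCCA) rested on 1 control count and was 26.3-fold higher (95% counting interval 4.12 to 1098, edgeR adjusted p = 0.0035). DESeq2 gave it an adjusted p of 0.065. Like tRF_3_204, the fragments tRF_3_62 and tRF_5_387 differ by 1 base from a fragment that was more abundant in controls and did not pass. That fragment was tRF_3_61 for tRF_3_62 (log2 fold change 0.18, edgeR adjusted p = 0.88). For tRF_5_387 it was tRF_5_388 (0.31, edgeR adjusted p = 0.78). The rarer tRF_5_114 differs by 2 bases from tRF_5_112, which also rose.

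Among 5′ fragments, tRF_5_112 (GTTTCCGTAGTGTAGTGGTCATC, valine, anticodon CAC) rose from 47.4 ± 33.9 to 1372 ± 554 CPM (SD, n = 3; log2 fold change 4.84 ± 0.81 SE, edgeR adjusted p = 0.00064). Its form longer by 1 nt, tRF_5_132, was 36.3-fold higher (95% counting interval 9.51 to 309, 2 control counts). The 18-nt lysine fragment tRF_5_34 (GCCCGGATAGCTCAGTCG, anticodon TTT) rose from 23.7 ± 16.9 to 640 ± 275 CPM (SD, n = 3; log2 fold change 4.71 ± 0.86 SE, edgeR adjusted p = 0.00098). Also with 2 control counts each were the fragments tRF_5_387 (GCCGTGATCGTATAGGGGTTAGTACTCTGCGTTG), 57.2-fold higher with a 95% counting interval of 15.3 to 481, and tRF_5_114 (GTTTCTGTAGTGTAGTGGTTATC), 23.2-fold higher with an interval of 5.88 to 200; their tRNAs were not assigned. The trailer with the lowest p was tRF_1_332 (CTCTCTCACTTTTAAGTAATTCTTTT), at 7.23 ± 6.71 CPM in control and 105 ± 37.0 CPM in knockout hearts (SD, n = 3; log2 fold change 3.72 ± 0.85 SE, edgeR adjusted p = 0.0035). The other 3 called trailers, tRF_1_265, tRF_1_312 and tRF_1_69, were named after their values were seen and rose by 2.85 ± 0.85, 3.49 ± 0.94 and 3.02 ± 0.83 (SE) on the log2 scale. The call of tRF_1_265 was lost by DESeq2 (adjusted p = 0.072). It was also lost with no filter and without control replicate 2 or knockout replicate 1 or 3 (edgeR adjusted p from 0.057 to 0.15). That of tRF_1_69 was lost without knockout replicate 1 (edgeR adjusted p = 0.056). The 1 CCA-ending fragment called lower was tRF_3_200 (TCGAGCCCCAGTGGAACCACCA), named on the same basis, with a log2 fold change of −2.24 ± 0.78 (SE, edgeR adjusted p = 0.037) and 370, 53 and 49 control counts. Its call was lost without control replicate 1, where the log2 fold change was −1.08, and without knockout replicate 1, 2 or 3 (edgeR adjusted p from 0.082 to 0.15). It was also lost with upper-quartile scaling, library totals and the replicate block (edgeR adjusted p = 0.053, 0.56 and 0.063) and by limma-voom (adjusted p = 0.10).

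The reported fragments with the largest falls were 5′ fragments of 27 to 29 nt, from glycine tRNAs and from tRNAs that were not assigned. Of 26 tested 5′ fragments of 27 to 29 nt, 20 were lower (median log2 fold change −3.22, and −0.84 with library totals alone). So were 12 of 18 of 36 nt or longer (median −3.78, and −0.80 with library totals alone). The glycine fragment tRF_5_178 (GCATTGGTGGTTCAGTGGTAGAATTCT, 27 nt) fell from 47806 ± 5019 to 1017 ± 168 CPM (SD, n = 3), a log2 fold change of −5.55 ± 0.75 (SE) with edgeR adjusted p = 0.0002. The 28-nt glycine fragments tRF_5_195 and tRF_5_196, both among the 5 most abundant sequences, had log2 fold changes of −4.03 ± 0.83 and −4.63 ± 0.89 (SE). Sequences of an unassigned tRNA that starts with GGCTCGTT included 4 of the 10 largest falls among called fragments whose groups did not overlap: tRF_5_232 at −5.77 ± 0.92, tRF_5_231 at −5.62 ± 1.05, tRF_5_203 at −4.71 ± 0.83 and tRF_5_183 at −4.04 ± 0.80 (SE). The unassigned fragments tRF_5_234 (GGTCCCATGGTGTAATGGTTAGCACTCTG) and tRF_5_217 (GCATGGGTGGTTCAGTGGTAGAATTCTCA) fell by 5.58 and 4.17 on the log2 scale. With library totals alone, tRF_5_217 and tRF_5_183 were no longer called, at edgeR adjusted p = 0.12 and 0.15.

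The most abundant fragment was tRF_5_284 (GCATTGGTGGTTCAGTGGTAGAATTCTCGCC), the 31-nt 5′ fragment of a glycine tRNA with anticodon GCC, which took 45.5% to 60.0% of all tRF counts in each of the 6 libraries. Its log2 fold change was −2.55 ± 0.91 (SE, edgeR adjusted p = 0.042), but that call was fragile: adjusted p was 0.054 with size factors of DESeq2, and with library totals alone the log2 fold change was 0.02. It was also lost without control replicate 2 or 3 and without knockout replicate 1, 2 or 3, at edgeR adjusted p from 0.053 to 0.25. The glycine fragment tRF_5_254, shorter than tRF_5_284 by 1 nt, had a log2 fold change of −0.95 ± 0.66 (SE) and did not pass the test (edgeR adjusted p = 0.32); with library totals alone it was 1.06.

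**Figure D2:**
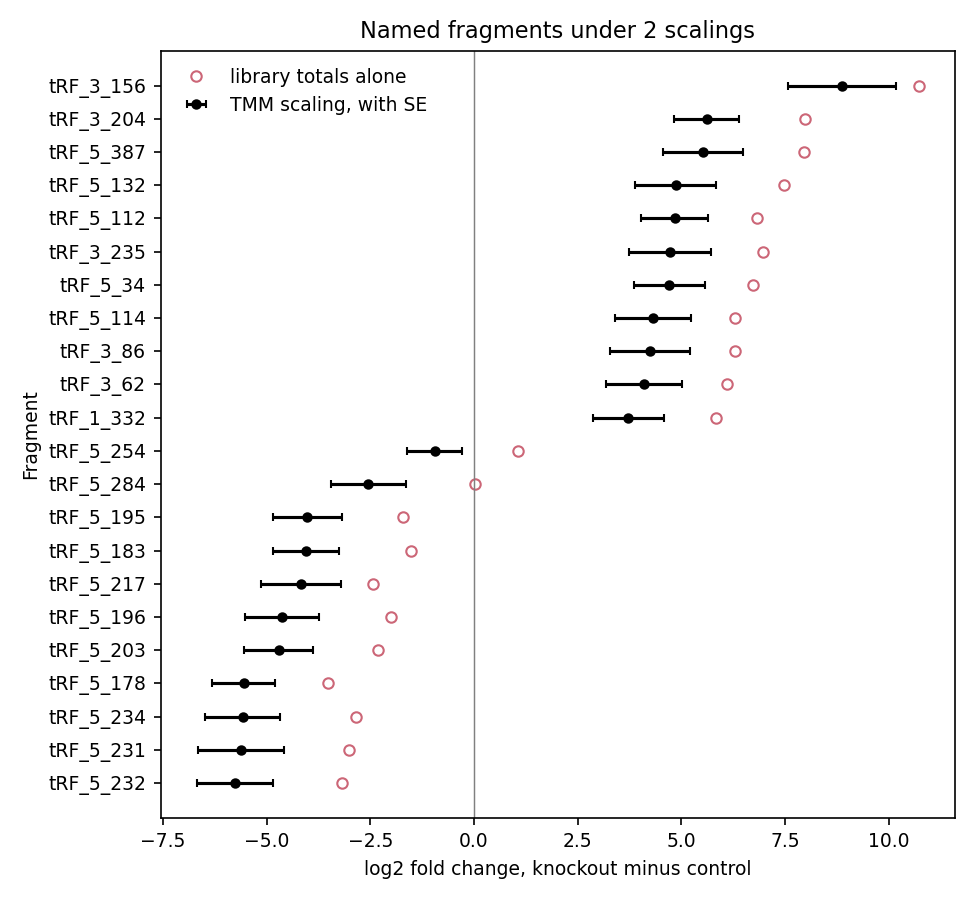
Log2 fold changes, knockout minus control, on the x axis for 22 of the 24 fragments chosen by a fixed rule, with TMM scaling and its SE in black and library totals alone as open red circles (n = 3 mice per group). The fitted value of tRF_3_156 depends on a prior count because its control counts are 0. The 2 fragments whose direction turned with the scaling are tRF_5_284 and tRF_5_254.

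Fragment classes were then compared as sets. 5′ fragments lay lower than the other tested fragments (median log2 fold change −0.61, camera adjusted p = 0.0028), CCA-ending fragments lay higher (median 0.29, camera adjusted p = 0.024), and trailers had a median of 0.29 with camera adjusted p = 0.086. With an estimated correlation the adjusted p was 0.49 for each class. fry, which tests whether a class moves on balance 1 way, gave adjusted p = 0.45, 0.12 and 0.13, whereas its test for change in either direction gave adjusted p = 0.00039, 0.00014 and 0.0018. The 5′ call was lost without control replicate 2 (adjusted p = 0.11), and the CCA-ending call without control replicate 2 or 3 or knockout replicate 1 or 3 (adjusted p from 0.072 to 0.15). With library totals alone all 3 medians were above 0 (1.78 for 5′ fragments, 2.21 for CCA-ending fragments and 2.37 for trailers), and 5′ fragments lay 0.38 below the median of all tested fragments. The sign of the CCA-ending median depended on the filter. With no filter the medians were −0.62 for CCA-ending fragments, −0.02 for trailers and −1.13 for 5′ fragments. DESeq2, also run without that filter, gave −0.38, 0.16 and −0.48.

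By tRNA, of 24 glutamate 5′ fragments 12 were lower and 0 higher, with a median log2 fold change of −1.85, which turned to 0.28 with library totals alone. As a set they lay lower than the other tested fragments at a preset correlation (camera adjusted p = 3.9e-06), but not with an estimated correlation (adjusted p = 0.25), and fry gave adjusted p = 0.053. By edgeR at an unadjusted p under 0.05 there were 14 lower and 0 higher, by DESeq2 12 and 0 and by limma-voom 8 and 0. The glutamate families that start with TCCCATATGGTCTAG and TCCCACATGGTCTAG had log2 fold changes of −3.15 ± 0.63 and −2.91 ± 0.66 (SE; edgeR adjusted p = 0.0041 and 0.0078). With library totals alone these were −0.52 and −0.23 and no longer called (edgeR adjusted p = 0.55 and 0.78). Fragments with these starts fell more at 27 to 29 nt than at 30 to 32 nt. The medians at the 2 lengths were −3.19 and −1.37 for TCCCATAT, and −2.81 and −0.87 for TCCCACAT. Of 29 glycine fragments 17 fell and 8 rose, with a mean of −1.18 and a median of −2.20, which turned to 0.23 with library totals alone. The camera adjusted p was 0.0029, against adjusted p = 0.44 with an estimated correlation and 0.11 by fry. By start sequence, all 7 fragments that start with GCATTGGTAGTTCAA, from a tRNA with anticodon CCC, rose in the edgeR test (median 3.34; 6 by DESeq2 and 5 by limma-voom). Both that start with GCATTGGTGGTTCAA, also read as CCC, fell (median −3.49), and 14 of 16 that start with GCATTGGTGGTTCAG fell (median −3.08). Summed over its 41 sequences, that last family did not pass (log2 fold change −3.08 ± 1.29 SE, edgeR adjusted p = 0.13). The 2 falling fragments read as CCC, tRF_5_194 (28 nt) and tRF_5_283 (31 nt), end before base 33, where the families next differ. Their anticodon was thus carried from a longer sequence. Each differs by 1 base from an abundant fragment of that last family, tRF_5_195 or tRF_5_284. The log2 fold changes were −3.73 against −4.03, and −3.25 against −2.55. Sequencing errors of the abundant family stay open as their source. The 4 that start with GCGCCGCT went both ways, with 1 higher, 1 lower and 2 not called, from −2.10 to 2.16. Of 23 valine fragments 9 rose and 3 fell (median 0.90, camera adjusted p = 0.046; adjusted p = 0.61 with an estimated correlation and 0.13 by fry). The summed valine families that start with GTTTCCGTAGTGTAG and GGTTCCATAGTGTAG did not pass, at −0.70 ± 0.73 and 0.03 ± 0.60 (SE; edgeR adjusted p = 0.56 and 1.0). The valine fragments included tRF_5_334 at 3.10 ± 0.76 and tRF_5_242 at −2.02 ± 0.64 (SE), of which the latter was 0.22 with library totals alone. The call of tRF_5_242 was also lost without control replicate 2 or 3 or knockout replicate 1 or 2 (edgeR adjusted p from 0.053 to 0.23). The set that starts with GGCTCGTT had 5 lower and 0 higher of 7 by edgeR, at an unadjusted p under 0.05 and by DESeq2, and 4 lower and 0 higher by limma-voom. Its median was −4.04 (camera adjusted p = 0.0029, with adjusted p = 0.52 at an estimated correlation and 0.11 by fry). That fall depended on length: the median was −5.17 at 27 to 29 nt (4 fragments) and −0.09 at 30 to 32 nt (3 fragments). Serine fragments had 3 higher of 8 (median 1.74, camera adjusted p = 0.075), those starting with GCCGTGAT had 3 higher and 2 lower of 15 (adjusted p = 0.15), and lysine fragments had 2 higher and 1 lower of 18 (adjusted p = 0.57). With an estimated correlation, or by fry's test for a move on balance 1 way, none of the 7 sets passed. Its test for change in either direction gave adjusted p from 0.00038 to 0.0185. Against the median of all tested fragments, the glutamate and glycine medians with library totals alone were −1.88 and −1.92.

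A subset of fragments could be placed in the genome. In GRCm38, 67 sequences matched 10 of 403 annotated tRNA genes, and 5 of the called fragments were among them. The gene n-TSgct5, a serine tRNA on the minus strand of chromosome 13 from 22050686 to 22050767, holds tRF_5_47, tRF_5_60 and tRF_5_76 at its 5′ end and lies within an exon of the unclassified transcript Gm48356. These fragments of 19, 20 and 21 nt rose by 2.02 ± 0.73, 3.15 ± 0.99 and 2.88 ± 0.88 (SE) on the log2 scale (edgeR adjusted p = 0.044, 0.021 and 0.018). DESeq2 called tRF_5_60 (adjusted p = 0.039) but not tRF_5_47 or tRF_5_76 (adjusted p = 0.20 and 0.15). The call of tRF_5_47 was lost when any 1 library was left out (edgeR adjusted p from 0.064 to 0.15). That of tRF_5_76 was lost without control replicate 3 or knockout replicate 1, 2 or 3 (edgeR adjusted p from 0.052 to 0.11), and that of tRF_5_60 without knockout replicate 3 (edgeR adjusted p = 0.12). The gene n-TGccc7, a glycine tRNA on the plus strand of chromosome 17 from 25875088 to 25875158 within an exon of a transcript of the protein-coding gene Mettl26, holds tRF_5_325 and tRF_5_420. The 32-nt fragment tRF_5_325 rose by 2.16 ± 0.76 (SE), and the 35-nt fragment tRF_5_420, which starts at the same base, had a log2 fold change of −2.10 ± 0.78 (SE; edgeR adjusted p = 0.037 and 0.049). By DESeq2 tRF_5_325 was not called (adjusted p = 0.30), and with library totals alone tRF_5_420 was 0.23 and not called (edgeR adjusted p = 0.82). Neither was called without knockout replicate 1, 2 or 3 (edgeR adjusted p from 0.10 to 0.25), nor tRF_5_420 without control replicate 2 (edgeR adjusted p = 0.078).

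**Figure D3:**
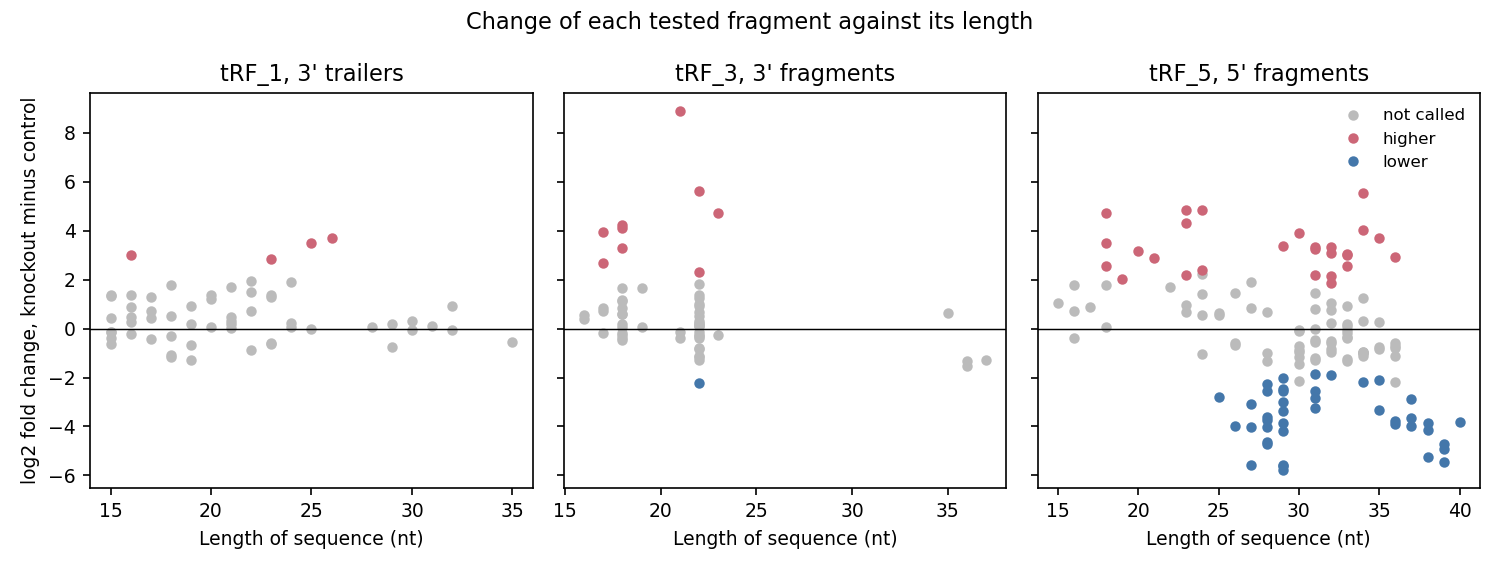
Log2 fold change, knockout minus control, on the y axis against fragment length in nt on the x axis, in a panel for each class; each point is 1 of the 254 tested fragments, red where higher, blue where lower and grey where not called (n = 3 mice per group, TMM scaling). Of 26 tested 5′ fragments of 27 to 29 nt, 20 were lower and 1 higher; of 19 of 15 to 23 nt, 9 were higher and 0 lower (11 and 0 at an unadjusted p under 0.05, 5 and 0 by DESeq2, 9 and 0 by limma-voom).

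In the authors' deposited table, 90 fragments had an adjusted p under 0.05, 29 higher and 61 lower in the knockout. The authors' deposited table and the edgeR test shared 69 called fragments, all in the same direction. Of the remaining calls in the authors' deposited table, 20 were of fragments that did not pass the filter here and 1 was tested and not called, while 14 were called only here. By class, the authors' deposited table called 4 trailers higher, 7 CCA-ending fragments higher and 2 lower, and 18 5′ fragments higher and 59 lower.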

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

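The sums over families were chosen after seeing the data. The count of 83 called fragments lay between 59 and 111 over the settings chosen before the data were examined, within 1.5 times, and was 17 (8 higher, 9 lower) when nested sequences were summed into families, which leaves fewer units to test. Over families the split was 35 and 0 with library totals alone, 7 and 7 with upper-quartile scaling and 6 and 8 with size factors of DESeq2. The split moved to 104 higher and 7 lower with library totals alone and to 25 higher and 74 lower with no filter; leaving out 1 library gave 59 to 91 calls, 30 to 49 higher and 26 to 42 lower. Scaling by totals is itself driven by the most abundant 5′ fragments; for the other shifts the cause was not tested. Of 24 named fragments, 17 kept direction and call under each alternative that gave a value. With library totals alone tRF_5_284 reversed to 0.0203 and tRF_5_254 to 1.06. For the classes, an estimated correlation gave adjusted p = 0.49 and left 0 sets past 0.05 of 2; fry also left 0, with 0.12 for CCA-ending and 0.45 for 5′ fragments; with no filter CCA-ending fragments had 0.22 and trailers 0.041. Leaving out 1 library gave adjusted p from 0.021 to 0.35 for trailers, 0.00052 to 0.15 for CCA-ending and 1.0e-05 to 0.11 for 5′ fragments, and 0 to 3 sets. Of the tRNA sets, 4 passed in the main test, 0 with an estimated correlation or by fry's test for a move on balance 1 way, and 10 with no filter. Shares without the most abundant fragment differed by 11.5, 12.1 and −23.6 percentage points. Sums per anticodon were not run, as the names give none. With the replicate block 66 fragments were called, 64 of them shared. Same-numbered libraries deviated together with correlations of −0.05, 0.27 and 0.02, and 2 of 6 libraries correlated best with their own number. With 3 libraries per group these values cannot tell whether the numbers mark pairs, and the labels name no batch, day or litter. Under the block tRF_5_284 had adjusted p = 0.11. In the simulation, changes of 2 on the log2 scale were recovered in 33.3% of cases, so many changes of this size or smaller may be missed. The simulation gave each sequence the same dispersion, so recovery in these libraries may differ.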

Other observations

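In a valine precursor the trailer and the mature 3′ end could be set side by side; this comparison, and each test in this part apart from the count of other splits, was chosen only after the result was seen. The longest sequence, of 96 nt, carries a whole valine tRNA with anticodon TAC and its trailer, and with a slightly shorter form it had 0 counts over the control and 3 over the knockout libraries. The 15 trailer sequences that begin at its cut site or 1 nt further summed to 414, 310 and 797 counts in control and 840, 917 and 940 counts in knockout libraries. The 9 CCA-ending fragments of the same tRNA body summed to 379, 58 and 51 counts in control and 30, 14 and 15 counts in knockout libraries. Of these, tRF_3_200 alone had 370, 53 and 49 control counts and 30, 12 and 15 knockout counts. It is the fragment called lower above, and the trailers include tRF_1_265, called higher above. The comparison is therefore not separate from those calls. The log2 ratio of trailer to CCA-ending counts, which needs no scaling between libraries, was 2.17 ± 1.93 (SD, n = 3) in control and 5.60 ± 0.69 (SD, n = 3) in knockout hearts (exact two-sided permutation test, p = 0.10, the smallest that 3 against 3 allow). Without control replicate 1 the control mean was 3.19 and the change dropped from 3.43 to 2.41. Whether other gene copies also give the CCA-ending sequences was not tested.

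The direction of change differed with the length of 5′ fragments: those of 15 to 23 nt went from 0.111% ± 0.0769 (SD, n = 3) of all 5′ counts in control to 1.79% ± 0.549 (SD, n = 3) in knockout hearts, and those of 27 to 29 nt from 25.2% ± 9.97 to 8.89% ± 1.30 (SD, n = 3), while those of 30 to 32 nt went from 58.1% ± 4.54 to 76.0% ± 8.21 and those of 33 to 35 nt from 1.78% ± 0.617 to 5.94% ± 2.25 (SD, n = 3; exact two-sided permutation test, p = 0.10 for each, the smallest possible). Those of 24 to 26 nt (0.362% ± 0.404 and 0.772% ± 0.216) and of 36 nt or longer (14.5% ± 14.8 and 6.58% ± 4.81) overlapped between the groups (SD, n = 3; exact two-sided permutation test, p = 0.30 and 0.40), and their control means were 0.130% without control replicate 1 and 6.44% without control replicate 2. A size selection that differed between libraries would shift trailers of the same lengths alike. The log2 odds of 23 nt or shorter against longer changed by 4.37 in 5′ fragments and 0.42 in trailers (trailer SDs 0.56 in control and 0.35 in knockout). Those of 27 to 29 nt against 30 to 32 nt changed by −1.82 and −0.19 (trailer SDs 0.61 in each group). The difference between the classes changed by 3.95 (SDs 0.99 and 0.59) and −1.63 (SDs 0.29 and 0.71). This argues against size selection as the whole account. A smaller part is not excluded, because both trailer changes went the same way as those of 5′ fragments. Groups of 5′ fragments that share the first 8 nt and hold both lengths had a lower median at 27 to 29 nt in 9 of 9. The difference was −2.56 ± 1.13 (mean and SD over groups). A different mix of these groups at the 2 lengths is therefore also argued against. A different mix within a group stays open, because the largest glycine group pools start sequences that rose with others that fell. The valine group likewise pools close variants that moved apart. Further open hypotheses are a difference in cleavage or decay of 5′ fragments between the genotypes and a library batch that followed genotype, which the labels do not name.

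Close sequence variants moved apart in places: among 63 pairs of tested fragments of the same class and length that differ by at most 2 bases, 20 had both members called and 4 of these went in opposite directions, such as tRF_5_239 at 3.39 ± 0.80 and tRF_5_242 at −2.02 ± 0.64 (SE; substitutions T20C and T27C from the second to the first, counted from the 5′ end); 2 such pairs were called with size factors of DESeq2, 1 with upper-quartile scaling and 0 with library totals alone, where tRF_5_242 was 0.22. Ratios within a library need no scaling: against the abundant glycine family that starts with GCATTGGTGGTTCAG, the log2 ratio of counts of the rising family that starts with GCATTGGTAGTTCAA (G9A and G15A) went from −12.23 ± 0.33 in control to −6.91 ± 1.73 in knockout hearts, and that of tRF_5_239 to tRF_5_242 from −8.42 ± 0.63 to −2.80 ± 0.19 (SD, n = 3; exact two-sided permutation test, p = 0.10 for each, the smallest possible). Sequencing errors at a fixed rate would keep their ratio to the parent. The change of 5.31 (6.31 without knockout replicate 3) therefore argues against errors as the source of the rising family. For the falling family that starts with GCATTGGTGGTTCAA (G15A) the values did not settle this, and errors stay open. Its log2 ratio to the abundant family was −10.11 ± 0.26 in control and −10.70 ± 0.55 in knockout hearts (SD, n = 3), with overlapping groups (exact two-sided permutation test, p = 0.20). At 32 nt or shorter the ratio changed by −0.58, against summed SDs of 0.40. Of its 174 counts of 33 nt or longer, 0 carry the G of the abundant family at base 33. That cannot decide, because the rule for listing sequences is not given and forms with that G may not have been listed. A variant lacking in controls is argued against by the share of the rising against the abundant family in controls, which on the log2 scale was higher by 6.24 ± 0.88 (SD, n = 3) at 35 nt than at 31 nt, where errors in the first 15 nt would give the same share; carry-over from knockout libraries would need 18.3% of their count, while tRF_3_156 had 0 counts in controls against 134 in knockouts. Different use or processing of tRNA gene copies may account for the rise, as an untested hypothesis; unequal frequency of a variant between the mice stays open too.

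With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 83 fragments, and 1 of the 10 splits called as many, the real one itself; the highest of the others called 0.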
